A study of Mus musculus with 2 samples.

How the data were processed

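Gene expression was measured in single cells of the mouse celiac and superior mesenteric ganglia, the prevertebral sympathetic ganglia that supply abdominal organs. The series holds 2 libraries of 1 group, made with 10x Genomics 3' chemistry from digested and triturated tissue. The series text states that 20 animals aged 7 to 8 weeks were used, with the sexes in equal number. Which animals went into which library is not given in the sources used here. P-values therefore rest on the spread between these libraries, largely as shared over genes, and this spread may be technical only.

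The deposited values are raw counts, that is, numbers of unique molecular identifiers (UMIs) per gene and cell barcode, without normalization. Cell Ranger 6.1.2 and the mouse genome build mm10 are named in the submitters' processing notes. The annotation release and the cell filters of the submitters are not given in the sources used here. Library 1 held 12594 barcodes and 94521010 UMIs over 32183 genes, with 1501 to 44696 UMIs per barcode. Library 2 held 12279 barcodes and 95235439 UMIs, with 1501 to 44898 UMIs per barcode. The highest mitochondrial share of a barcode was 9.995% in library 1 and 9.998% in library 2. Gene coordinates and gene types were taken from GENCODE M21 on GRCm38, the same assembly as mm10. Whether reads were counted by strand is not given in the sources used here, so the levels of antisense genes that overlap other genes are uncertain. Whether reads in introns were counted is not given there either. An upper bound on UMIs may have removed large neurons before deposition.

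The tests, gene lists, naming rules and alternatives were fixed before the data were examined, except where a later choice is named as such. Cells with at least 500 genes, at least 1000 UMIs and under 20% mitochondrial UMIs were kept. Doublets were scored by the Scrublet method in scanpy 1.11.5 within each library, at its automatic threshold. It marked 663 cells (5.26%) of library 1 and 710 cells (5.78%) of library 2, and these were removed. Of library 2, 1 barcode had under 500 genes, and it was among those marked as doublets. The remaining 11931 and 11569 cells were analysed. Each cell's UMIs were split at random, with probability 0.5, into UMIs for clustering and naming and UMIs for testing, so that no gene was tested on the UMIs that formed the clusters. The log of counts per 10000, 3000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (leidenalg 0.10.2) at resolution 1, without integration of the libraries. This gave 28 clusters, which were named by 28 sets of marker genes. Names of cell types are used for cells like those types by markers. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, anndata 0.12.19, statsmodels 0.14.6 and matplotlib 3.10.9 was used.

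The 1685 neuron-like cells were clustered again at resolution 0.8, without Shox2, Rxfp1, mitochondrially encoded, ribosomal protein, haemoglobin, sex-linked, immediate early and other-cell genes. A neuron cluster was noradrenergic if its Th and Dbh levels each reached 0.25 of the highest neuron cluster. The Shox2 level of each cluster was divided by the highest level among the noradrenergic clusters not left out by the rules below. The Rxfp1 level was treated likewise. The Shox2 fraction minus the Rxfp1 fraction had to exceed 0.25 in both libraries for a Shox2-rich cluster. It had to lie below -0.25 in both for a Rxfp1-rich cluster. A cluster counted as led by markers of other cells if its genes of largest fold held several markers of another cell class, and more of these than of neurons. Such markers did not have to be among its 10 leading genes. These clusters were left out of the populations, as was a cluster whose median UMI count lay below 1/3 of that of its library with no neuron marker among its 10 leading genes.

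The UMIs for testing were summed per library and population, and each comparison rested on 4 sums, a pair from each library. Genes were filtered with filterByExpr, scaled by the trimmed mean of M-values (TMM) and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the library as a block. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. The block left 1 residual degree of freedom per gene, so the fit drew the spread of a gene largely from all genes. The prior degrees of freedom for this were 9.338 for neurons and 154.8 for the glia. They were infinite for the neuron populations, where the spread of a single gene between the libraries carried no weight in its p-value. Levels are given as CPM, UMI counts scaled to 1000000 tested UMIs per population and library, as mean ± SD over the 2 libraries. Log2 fold changes carry the standard error (SE) of the fit. Log2 values of single libraries are ratios of CPM with nothing added, except in medians over a list and in the alternatives that leave out a library, where 1 CPM was added to both populations. A fold against a population without a UMI was computed against a floor of 3 counts over that population, and a ratio against 1 to 3 counts carries its 95% counting interval. Shares of cells carry exact (Clopper-Pearson) 95% binomial intervals. All such intervals and floors cover counting error only. Cells were not used as replicates in any test of genes. Only the intervals for neurons paired by UMIs, given in the last paragraph, came from resampled cells.

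The comparisons were neurons against non-neuronal cells, Shox2-rich against Rxfp1-rich neurons, each neuron cluster against the other neurons, and satellite glia against Schwann cells, myelinating and non-myelinating together. The genes named are those with the largest log2 fold change among genes past the threshold, changed the same way in both libraries and with at least 20 CPM in the higher population in both libraries. The rule took 10 genes per direction for neurons, 15 per direction for the neuron populations, with Shox2 and Rxfp1 always named, the 3 largest upward for each neuron cluster and 8 per direction for the glia. Gene models without a name of their own were skipped. In each gene list, the 4 members with the smallest p-value among those with at least 20 CPM in either population were also named, except a few that are not reported here but were kept in all tests and list counts.

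The 20 gene lists were noradrenergic synthesis, storage and reuptake; sympathetic transcription factors; Hox genes; cholinergic transmission; neuropeptides and granins; acetylcholine receptors; adrenergic receptors; peptide and hormone receptors; amine, purine, GABA and glutamate receptors; voltage-gated ion channels; TRP and mechanosensitive channels; axon guidance; cell adhesion; neurotrophic factor receptors; immediate early and dissociation response; axon injury response; mitochondrially encoded genes; and 3 lists of satellite glia, fibroblast and immune RNA in neuron droplets. The first 17 were also tested in neurons against non-neuronal cells. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset inter-gene correlation of 0.01, two-sided, and again with an estimated correlation. The estimated setting rested on 1 residual degree of freedom, so it had little power to pass any list.

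The alternatives were RLE size factors, no low-count filter, DESeq2 1.42.0, no library block, all UMIs, another random split and each library left out. For the neuron populations they were single neurons chosen by Shox2 and Rxfp1 UMIs, resolution 0.4, neurons with at least 5000 UMIs, and neurons thinned to 1000 UMIs. For the shares of cells they were at least 1000 genes, doublets kept, clusters from all UMIs and under 10% mitochondrial UMIs. Chosen after seeing the data were neurons with at most 0.5% of UMIs from the lists of other-cell RNA, neurons of the Shox2-rich and Rxfp1-rich clusters alone against non-neuronal cells, glia without the cluster led by Ifit3, satellite glia against non-myelinating Schwann cells alone, and clusters past the Shox2 margin counted as Shox2-rich, namely that with few UMIs in the test and the share, and all of them in the share. The tests were checked on simulated data, with 200 genes changed in UMI sums of the same size. Every simulated gene had the same dispersion and no difference between libraries, so the check does not cover genes that depart from this. Of genes changed 2-fold, 70.5% were recovered for neurons, 51% for the neuron populations and 83.5% for the glia. Of genes changed 4-fold, 86%, 96.5% and 97% were recovered, with 3 to 7 false calls per run, and no gene was called when none was changed.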

Results

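Single-cell RNA levels were measured in 2 libraries of the mouse celiac and superior mesenteric ganglia, the sympathetic ganglia whose axons reach the stomach, intestine, liver, pancreas and spleen. Both libraries belong to 1 group, so the comparisons are between cell populations within the same suspensions. Library 1 held a median of 6483 UMIs and 2630.5 genes per barcode, and library 2 held 6498 UMIs and 2640 genes. Between the libraries, the median chi-square per gene was 1.05 in satellite glia and 0.966 in neurons, against 0.455 for counting error alone, which leaves out differences between cells, and the SD of the log2 ratio between the libraries was 0.14 and 0.22.

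Cells of 14 classes were found, and satellite glia, the cells that wrap neuronal somata, were the most frequent of them. Satellite glia made up 28.8% (95% interval 27.9 to 29.6) of library 1 and 27.9% (27.1 to 28.7) of library 2. Fibroblasts followed with 18.9% and 19.8%, non-myelinating Schwann cells with 10.6% in both libraries, macrophages with 9.17% and 9.34%, and blood endothelial cells with 8.13% and 7.55%. Neurons made up 7.32% (6.86 to 7.80), or 873 cells, of library 1 and 7.02% (6.56 to 7.50), or 812 cells, of library 2. Perineurial or epineurial cells took 5.90% and 5.39%, pericytes or smooth muscle cells 5.09% and 5.24%, dendritic cells 2.67% and 3.155%, and myelinating Schwann cells 1.67% and 1.85%. Mast cells, T cells, lymphatic endothelial cells and proliferating cells each stayed at or below 0.562% of either library. Satellite glia fell to 22.4% and 21.9%, and neurons to 4.05% and 3.91%, when doublets were kept, while cells in clusters without a name rose from 0.360% and 0.519% to 5.05% and 5.03%. The neurons named then numbered 510 and 480 although no cell was taken away, so clustering or its naming moved cells out of the class. No barcode held over 44898 UMIs, so the shares cover deposited barcodes only, and larger neurons would be missing if an upper bound was applied before deposition.

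**Figure D1:**
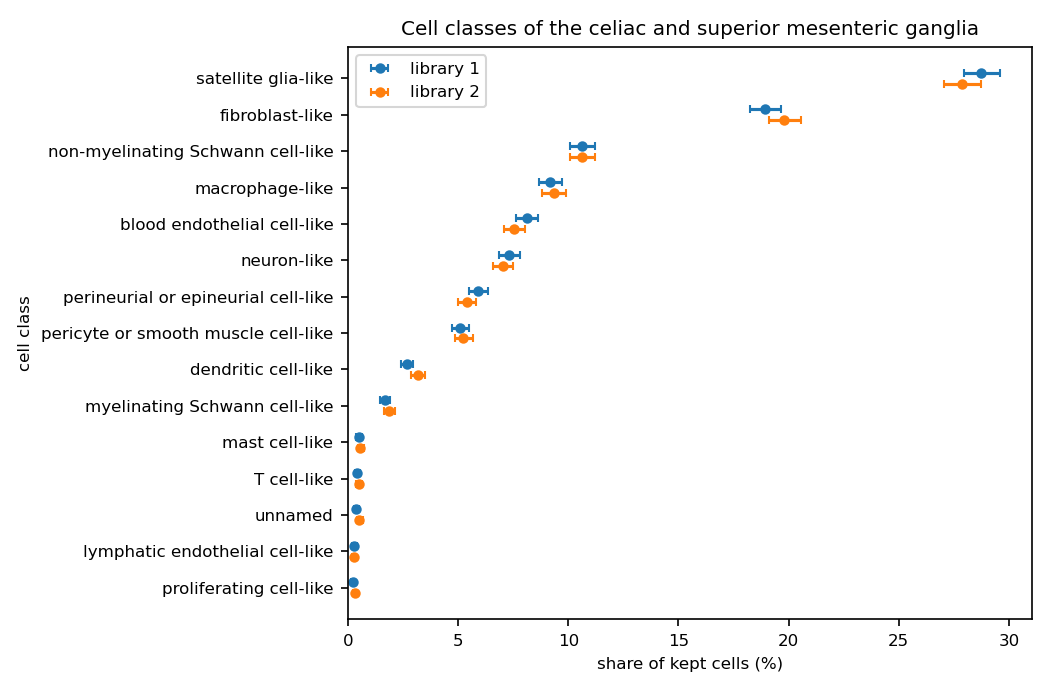
Share of kept cells (%, horizontal axis) in each cell class for library 1 and library 2. Points are single libraries and bars are exact 95% binomial intervals; satellite glia lie highest, at 28.8% and 27.9%.

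Immune genes led several of these clusters. A satellite glia cluster of 898 cells was led by Ifit3, Ifit1 and Isg15, and a fibroblast cluster of 143 cells by Plac8, Ifit3 and Isg15. A macrophage cluster of 127 cells was led by Folr2, a folate receptor, and also carried Lyve1, a hyaluronan receptor of resident macrophages. A cluster of 409 cells, named dendritic by its markers, was led by Retnla and Lyz1 and carried Cd209a but also Ccl6 and Ccr2, which monocytes and macrophages express as well. A class of monocytes was named when doublets were kept (0.508% and 0.546%) and with clusters from all UMIs (0.469% and 0.501%), where dendritic cells took 2.29% and 2.96%, and 2.01% and 2.498%. Another dendritic cluster, of 274 cells, was led by Irf8 and carried Xcr1, a chemokine receptor of cross-presenting dendritic cells. RNA of neurons was found in droplets of every abundant class. Th, the rate-limiting enzyme of catecholamine synthesis, stood at 83.7 CPM ± 3.84 in endothelial cells and 86.6 ± 1.49 in macrophages (SD, n = 2 libraries), against 317 ± 68.6 in Shox2-rich and 245 ± 49.8 in Rxfp1-rich neurons over all UMIs.

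Most neuron-like droplets held few UMIs. Of the 1685, a cluster of 718 had a median of 1810.5 UMIs and a cluster of 371 had 2781, whereas the Rxfp1-rich cluster of 129 cells had 22341 and the Shox2-rich cluster of 123 cells had 21373. Malat1, an RNA held in the nucleus, stood at 4784 and 7836 CPM in the former pair and at 81303 and 73031 CPM in the latter. On the UMIs for clustering, Th stood at 605 and 857 CPM in the former pair and at 245 and 317 CPM in the latter. Dbh stood at 1521 and 1424 CPM in the former pair and at 423 and 487 CPM in the latter. The Rxfp1-rich and Shox2-rich clusters thus passed the noradrenergic rule at lower levels than these low-UMI clusters. All 8 neuron clusters passed it, also those led by markers of other cells, so the rule set no cluster apart. Shox2-rich neurons made up 6.87% (5.29 to 8.76) of the neuron-like cells of library 1 and 7.76% (6.01 to 9.82) of library 2. Rxfp1-rich neurons made up 7.90% (6.20 to 9.90) and 7.39% (5.69 to 9.41). Among neurons with at least 5000 UMIs the shares were 25.2% and 32.1% for Shox2-rich and 29.0% and 29.5% for Rxfp1-rich neurons, so these shares depend on which droplets are counted as neurons. In library 2, Shox2 stood at 130, 145 and 99.8 CPM in the clusters of 718, 79 and 76 droplets, against 90.4 CPM in the Shox2-rich cluster. In library 1 these clusters had 124, 123 and 75.3 CPM, against 161 CPM in the Shox2-rich cluster. The clusters of 718 and 79 droplets also passed the Shox2 margin in both libraries. The former was left out because its genes of largest fold held 4 markers of another cell class against 1 of neurons. None of these markers stood among its 10 leading genes, so the Shox2-rich share leans on this rule. The latter was left out because it had few UMIs and no neuron marker among its leading genes. Counted as Shox2-rich, a choice made after seeing the data, the clusters of 718 and 79 droplets would raise that share to 52.9% and 56.4%.

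The comparison of neurons with the cells around them addressed which genes and receptors belong to the neurons of the ganglion. Cntn5, a contactin of the axonal surface, reached 2951 CPM ± 406 in neurons against 13.2 ± 0.418 in other cells (SD, n = 2 libraries), a log2 fold change of 7.67 (SE 0.0948). Rbfox1, a neuronal splicing factor, was 7.50 log2 units higher (SE 0.0756), and Nrg3, a neuregulin ligand of ErbB4, was 7.62 higher (SE 0.0879). Lingo2, Fam155a, Fgf14, Cntnap2 and Hs6st3 were higher by 7.06 to 7.45 log2 units. The largest values belonged to the antisense genes Nrg3os (9.76, SE 0.156) and Tmem132cos (7.80, SE 0.277, with 8.82 in library 1 and 7.36 in library 2), which are uncertain because strand use in counting is not given in the sources used here. Cntn5 lies on chromosome 9 from 9660891 to 10904775, Nrg3 on chromosome 14 from 38368952 to 39473088 and Rbfox1 on chromosome 16 from 5885355 to 7411526 (GRCm38). Among the genes lower in neurons, Itgam, an integrin chain of myeloid cells, had a log2 fold change of -5.13 in the fit, with 1.24 CPM against 20.9 in library 1 and 0 against 21.4 in library 2. Nostrin, which binds endothelial nitric oxide synthase, had a log2 fold change of -5.11, and Pdgfd, a platelet-derived growth factor, had -4.71, with 4.35 CPM against 69.9 in library 1 and 1.38 against 71.4 in library 2. Ifi213, Inmt, Ifi209, Rasgrp3, Cd84, Clec12a and Slc15a3 had values from -5.33 to -4.60, and each rested on 4 to 10 UMIs in neurons. Ifi213 had 1.24 CPM against 25.3 in library 1 and 0 against 23.2 in library 2. In library 1 and library 2, Clec12a had log2 values of -3.76 and -6.07, Ifi209 -4.09 and -5.97, Slc15a3 -3.81 and -5.55, Inmt -4.27 and -5.50 and Cd84 -4.02 and -5.17. With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 5819 genes were higher and 6776 lower in neurons of 18108 tested, and 3678 and 4568 of these differed by over 2-fold. Of the 12595 genes, 12573 had the same direction in both libraries, and DESeq2 called 8966, all among them. Clusters with a median under 5000 UMIs held 74.5% and 76.97% of the neuron-like cells of library 1 and library 2 but 23.5% and 25.8% of the tested UMIs. Clusters led by markers of other cells held 44.1% and 40.1% of these UMIs, so the neuron sums also carry RNA of other cells. In neurons of the Shox2-rich and Rxfp1-rich clusters alone, a comparison chosen after seeing the data, Hoxc9 (-0.13), Adra2a (-0.14) and mt-Co3 (-0.17) turned in direction and Adra2c (0.55) no longer passed.

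Genes of noradrenergic synthesis, storage and reuptake were higher in neurons: 10 of 12 tested rose and 2 fell. The vesicular monoamine transporter Slc18a2 was higher by 2.91 log2 units (SE 0.0785), the noradrenaline transporter Slc6a2 by 2.96, the decarboxylase Ddc by 2.59 and the monoamine oxidase Maoa by 2.43. Of voltage-gated ion channels, 45 rose, 13 fell and 3 did not pass, with Kcnip4, an auxiliary subunit of A-type potassium channels, higher by 6.87, Kcnq3 by 5.99, Kcnb2 by 5.57 and the N-type calcium channel gene Cacna1b by 5.37. Of acetylcholine receptors, 8 rose and 1 fell, and the muscarinic receptor Chrm2 (4.62) and the nicotinic subunits Chrna7 (3.66), Chrna3 (2.89) and Chrnb4 (2.77) were among those higher. Of neuropeptides and granins, 12 rose, 4 fell and 3 did not pass, with Pcsk1n (2.69), Npy (2.17), the prohormone convertase Pcsk2 (4.01) and Chga (2.71) higher. Of cell adhesion molecules, 40 rose, 14 fell and 8 did not pass, and Cntnap5a (5.80) and Cntn3 (6.99) stood beside Cntn5 and Cntnap2. Immediate early and dissociation response genes went the other way: 1 rose and 32 fell, including Jun (-3.15), Fos (-3.33), Egr1 (-3.54) and Fosb (-2.80). In camera with the preset correlation these lists had adjusted p-values of 0.00396, 1.05e-06, 0.00291, 0.0108, 6.75e-04 and 2.91e-07 in this order. None passed with an estimated correlation, where the adjusted p = 0.584 for each of the 6. That estimate rested on 1 residual degree of freedom and had little power to pass any list, so it cannot tell whether these lists hold.

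The other lists did not pass camera in this comparison. Sympathetic transcription factors had 13 members higher, including Tfap2b (3.67), Tbx20 (3.92), Isl1 (3.03) and Meis1 (2.97), and 7 lower, with an adjusted p of 0.0958. Of Hox genes, 6 rose, 15 fell and 3 did not pass, with Hoxc4 (1.94), Hoxc6 (0.74) and Hoxc9 (1.16) higher and Hoxa7 (-2.96) lower. Of cholinergic genes, Slc10a4 (2.28) and the acetylcholinesterase gene Ache (2.26) were higher and Prima1 (-2.31) was lower, and those for acetylcholine synthesis and vesicle loading, Chat and Slc18a3, had too few UMIs to test. Of adrenergic receptors, 3 rose, 2 fell and 2 did not pass, with Adra2c (1.63) and Adra2a (0.89) higher. Of peptide and hormone receptors, 18 rose, 17 fell and 4 did not pass. The secretin receptor gene Sctr (5.13) and the angiotensin receptor gene Agtr1a (2.67) were higher, and the genes of the vascular adrenomedullin receptor, Ramp2 (-2.97) and Calcrl (-3.89), were lower. Of amine, purine, GABA and glutamate receptors, 23 rose, 19 fell and 9 did not pass, with Grm7 (6.55), Gria2 (5.22) and Gria1 (4.75) higher. Of TRP and mechanosensitive channels, 10 rose, 5 fell and 3 did not pass, with Asic2 (6.33), Trpc7 (5.89) and Trpm3 (2.07) higher and Piezo2 (-4.03) lower. Axon guidance genes had 23 higher, 32 lower and 8 not passed, with Sema6d (5.34), Unc5c (6.15), Epha5 (4.95) and Dcc (6.16) higher. Of neurotrophic factor receptors, 5 rose, 11 fell and 3 did not pass. Ret (2.45) was higher, and Il6st (-2.27) and Gfra1 (-3.79) were lower. Of axon injury genes, 8 rose, 8 fell and 3 did not pass, with Gap43 (2.44) and Tubb3 (2.29) higher and Cdkn1a (-2.91) and Hspb1 (-1.80) lower. Of mitochondrially encoded genes, 5 rose, 4 fell and 4 did not pass, with mt-Nd6 (-0.58), mt-Co1 (-0.37) and mt-Atp8 (-0.50) lower and mt-Co3 (0.20) higher. Adjusted over the list alone, the counts differed only for Hox genes (6 higher, 16 lower), amine, purine, GABA and glutamate receptors (24 and 19) and cell adhesion molecules (41 and 14). The median and mean of adrenergic receptors (-1.38 and -1.26) were negative while camera ranked them upward, and mitochondrially encoded genes had a median of 0.12 and a mean of -0.03. The call of mt-Co3 also ended without the library block and without the low-count filter.

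The paper on this study names RXFP1 and SHOX2 populations of noradrenergic neurons, and the next comparison asked how the transcriptomes of such populations differ. Csmd3, a large membrane protein with complement-type domains, stood at 1016 CPM ± 10.4 in Shox2-rich and 2.54 ± 1.48 in Rxfp1-rich neurons (SD, n = 2 libraries), a log2 fold change of 8.44 (SE 0.277, adjusted p 1.17e-190 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), with 8.13 in library 1 and 9.42 in library 2. Kirrel3, a synaptic adhesion molecule, stood at 1236 CPM ± 170 against 27.8 ± 1.29, and the transcription factor gene Sox6 at 576 ± 57.7 against 14.7 ± 0.414. In the other direction Sctr, the receptor of the gut hormone secretin, had 3.43 CPM ± 4.85 in Shox2-rich and 589 ± 124 in Rxfp1-rich neurons, a log2 fold change of -7.29 (SE 0.286), with 0 CPM against 677 in library 1 and 6.87 against 501 in library 2. Dkk2, a secreted Wnt inhibitor, had no UMI in Shox2-rich neurons and 178 CPM ± 76.5 in Rxfp1-rich neurons, at least 83.6-fold lower in the former. In all, 426 genes were higher in Shox2-rich and 538 in Rxfp1-rich neurons of 8765 tested, 231 and 296 of them by over 2-fold, and 960 of the 964 had the same direction in both libraries. DESeq2 called 260, all among the 964, and with neurons thinned to 1000 UMIs the test called 114 of 1127.

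Shox2 itself, a homeobox transcription factor gene on chromosome 3 from 66971727 to 66981771, stood at 96.0 CPM ± 40.6 against 4.04 ± 0.632 (log2 fold change 4.51, SE 0.413), with 5.12 in library 1 and 3.91 in library 2. Rxfp1, the relaxin receptor gene on chromosome 3 from 79641611 to 79737880, stood at 67.6 CPM ± 16.0 against 353 ± 44.4 (-2.44, SE 0.179). The populations were defined by these genes on the UMIs that were not tested, so their differences were set by the definition. A UMI of Rxfp1 was found in 38.3% and 38.1% of Shox2-rich neurons of library 1 and library 2 and in 98.6% and 93.3% of Rxfp1-rich neurons. Blood endothelial cells, which served as background, gave 4.43% and 5.03% at median depths of 6982.5 and 7017.5 UMIs, against 18350.5 and 21745 in Shox2-rich and 23342 and 21495.5 in Rxfp1-rich neurons. Cells with at least 5000 UMIs were then thinned to 5000, which left out 363 of 970 and 330 of 874 endothelial cells, 1 Shox2-rich neuron and 3 Rxfp1-rich neurons. The Rxfp1 shares were 20.0% and 25.8% in Shox2-rich neurons, 68.1% and 70.2% in Rxfp1-rich neurons and 2.97% and 2.76% in endothelial cells, so Rxfp1 in Shox2-rich neurons lay above background although the definition favoured little Rxfp1 there. A UMI of Shox2 was found in 70.0% and 65.1% of Shox2-rich, 10.1% and 10.0% of Rxfp1-rich and 6.29% and 6.18% of endothelial cells. After thinning the Shox2 shares were 41.7% and 27.4%, 1.45% and 3.51%, and 5.11% and 3.86%. All these shares use the UMIs that defined the populations too, so the low share of Shox2 in Rxfp1-rich neurons was set in part by the definition.

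Other genes higher in Shox2-rich neurons included several of cell surfaces, as did the genes higher in Rxfp1-rich neurons given after them. The log2 fold change was 5.90 for the adhesion gene Igsf11, 5.81 for Lrp1b of the low-density lipoprotein receptor family, 5.02 for the protease gene Adamts19 (5.66 in library 1 and 4.67 in library 2), 4.93 for Pdzrn3, 4.71 for the heparan sulfate sulfotransferase gene Hs6st3, 4.53 for the adhesion gene Opcml and 4.51 for the adhesion gene Sdk1. It was 4.49 for Dab1, the adaptor of reelin signalling, with 5.23 in library 1 and 4.14 in library 2, and 4.33 for the phosphodiesterase gene Pde11a, with 3.86 and 5.38. Synpr, a synaptic vesicle gene with 1 UMI in Rxfp1-rich neurons, had a ratio of 134 (23.5 to 5319), and Vwc2, a secreted antagonist of bone morphogenetic proteins with 3 UMIs there, had a ratio of 73.2 (24.7 to 358), with log2 values of 6.94 in library 1 and 5.60 in library 2. Genes higher in Rxfp1-rich neurons included Lrrtm4 (-4.67), the nuclear receptor gene Rorb (-4.13), the semaphorin receptor gene Nrp1 (-4.04), the homeobox gene Hmx1 (-3.96), the atypical cadherin gene Fat4 (-3.93) and the tetraspanin gene Tspan8 (-3.88). Olfr78, an odorant receptor gene also known from the carotid body, had -3.84, followed by Cyyr1 (-3.83), Crispld1 (-3.80), the integrin gene Itga1 (-3.63), Banf2 (-3.62), Brinp2 (-3.62) and Zfp804a (-3.56). In library 1 and library 2, respectively, Lrrtm4 had -3.72 and -5.96, Hmx1 -5.56 and -3.19, and Cyyr1 -5.62 and -2.85. Csmd3 lies on chromosome 15 from 47580637 to 48792063, Kirrel3 on chromosome 9 from 34485894 to 35036716, Sctr on chromosome 1 from 120006894 to 120063536 and Dkk2 on chromosome 3 from 132085292 to 132180304 (GRCm38).

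**Figure D2:**
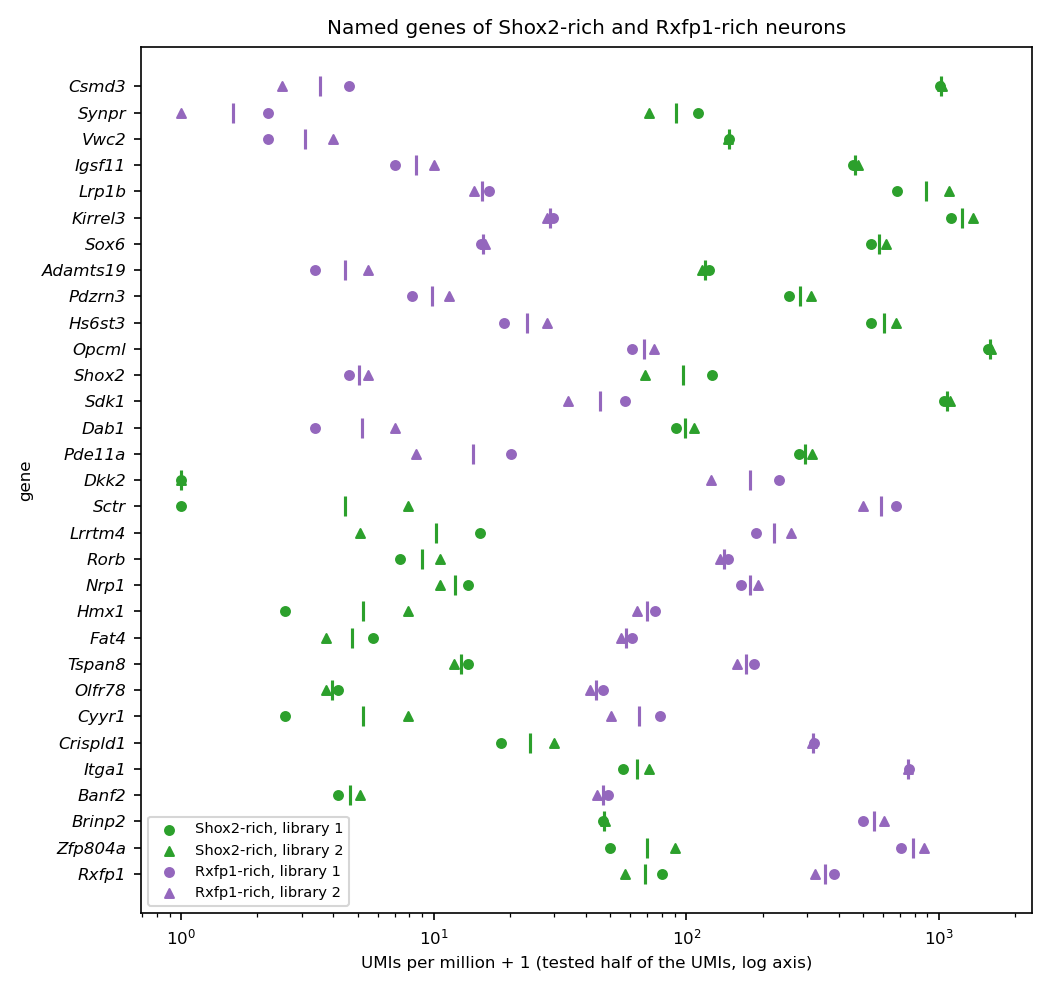
Level of each named gene (CPM of the tested UMIs plus 1, horizontal log axis) in Shox2-rich and Rxfp1-rich neurons. Circles are library 1, triangles library 2 and ticks their means; Csmd3 has means of 1016 and 2.54 CPM, and Dkk2 means of 0 and 178 CPM.

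The gene lists showed where the populations parted. Of acetylcholine receptors, none was higher in Shox2-rich neurons, 4 were lower and 3 did not pass. The nicotinic subunit genes Chrna7 (-2.16, SE 0.186), Chrna9 (-1.65) and Chrna5 (-2.06) and the muscarinic receptor gene Chrm2 (-0.42) were the lower ones. In library 1 and library 2, Chrna9 had -0.60 and -3.12 and Chrna5 had -3.19 and -1.36. Of axon guidance genes, 6 were higher, 12 lower and 13 not passed. Robo1 (-2.44), Nrp1 (-4.04) and Slit2 (-3.36) were lower, and the semaphorin gene Sema5a (3.33, with 4.08 in library 1 and 2.86 in library 2) was higher. Of immediate early and dissociation response genes, 8 were lower and 10 did not pass, including the transcription factor genes Fos (-1.66), Fosb (-1.83) and Junb (-0.98) and the antiproliferative gene Btg2 (-1.72). The median mitochondrial share, a mark of cell quality, was also higher in Rxfp1-rich neurons, at 1.57% in library 1 and 0.970% in library 2 against 1.23% and 0.764% in Shox2-rich neurons. Of the few Hox genes with enough UMIs, Hoxc6 (-0.84) was lower and 4 did not pass, including Hoxc8 (-1.19, adjusted p 0.0814), Hoxc4 (-0.56) and Hoxd4 (-0.63). In camera with the preset correlation these lists had adjusted p-values of 0.00522, 0.0328, 1.61e-05 and 0.0189 in this order. With an estimated correlation none of the 4 passed, at an adjusted p = 0.895 for each. Here too 1 residual degree of freedom left that setting little power, so it does not decide whether these lists hold.

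Cell adhesion molecules had the most members called in both directions: 14 higher, 18 lower and 13 not passed, with a median of -0.07 and a mean of 0.14. Beside Kirrel3 and Opcml, Lrrc4c, a netrin-G ligand of synapses, was higher (3.51), and Cntn5 was lower (-2.41). Of voltage-gated ion channels, 11 were higher, 7 lower and 27 not passed. The potassium channel genes Kcnd2 (1.96) and Kcnd3 (2.47) and the calcium channel gene Cacna1e (1.32) were higher, and Kcnh7 (-1.23) was lower. Of amine, purine, GABA and glutamate receptors, 5 were higher, 3 lower and 11 not passed. The glutamate receptor genes Grik1 (3.34, with 3.07 in library 1 and 4.05 in library 2) and Gria1 (1.09) and the prostaglandin receptor gene Ptger3 (1.25) were higher, and the serotonin-gated channel gene Htr3a (-1.93) was lower. Of peptide and hormone receptors, 4 were higher, 4 lower and 11 not passed. The somatostatin receptor gene Sstr2 was higher (2.56, with 3.40 in library 1 and 1.99 in library 2), as was the cholecystokinin receptor gene Cckar (1.97). Sctr was lower, and Oprd1, the delta opioid receptor gene, had no UMI in Shox2-rich neurons and 32 in Rxfp1-rich neurons, at least 9.66-fold lower. Of neuropeptides and granins, Chgb (0.95) was higher, 3 were lower and 8 did not pass. The lower ones were Pcsk2 (-3.36), Npy (-0.81) and Pcsk1n (-0.47). Of sympathetic transcription factors, 3 were higher, 3 lower and 9 not passed, among them Sox11 (1.44, with 1.01 in library 1 and 2.06 in library 2), Hmx1 (-3.96), Sox4 (-1.06) and Ebf1 (-0.58).

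Of the list of noradrenergic genes, Slc18a2 (0.60) and Cyb561 (0.67), which supplies the ascorbate electrons for noradrenaline synthesis, were higher in Shox2-rich neurons and 9 did not pass, including Maoa (0.29, adjusted p 0.124) and Dbh (0.28, adjusted p 0.204). Of neurotrophic factor receptors, Lifr (1.52) and Ntrk2 (2.12) were higher, Ret (-0.83) was lower and 8 did not pass, including Fgfr2 (-0.47). Of TRP and mechanosensitive channels, Asic2 (1.88) and Trpc6 (1.59) were higher, Trpm3 (-1.64) was lower and 6 did not pass, including Trpc7 (0.42). Axon injury genes had 2 higher, 3 lower and 8 not passed. Gap43 (0.52) was higher, and Csrp1 (-1.01), Hspb1 (-0.82) and Lmo7 (-2.90, with -2.09 in library 1 and -3.55 in library 2) were lower. Of mitochondrially encoded genes, mt-Atp6 (-0.38) and mt-Co3 (-0.33) were lower and 11 did not pass, including mt-Co1 (-0.31) and mt-Nd4 (-0.26). Of cholinergic genes, Slc10a4 (-0.50) and Ache (-0.26) did not pass, and none of the 2 tested adrenergic receptors passed. Among markers of other cells, Col1a2 of fibroblasts was higher (1.11, with 2.12 in library 1 and 0.25 in library 2). Of satellite glia RNA, 1 member was lower. The other 6 tested, including Dbi (0.30), Matn2 (0.37) and Sparc (0.15), 5 of fibroblasts, including Igfbp6 (-1.28), Dcn (0.42) and Col1a1 (0.56), and 2 of immune cells, Cd74 (-0.27) and Apoe (0.06), did not pass. In library 1 and library 2, Matn2 had 0.057 and 1.14, Igfbp6 -0.050 and -2.71, Col1a1 1.34 and -0.58, and Cd74 -0.85 and 1.46. The lists of satellite glia, fibroblast and immune RNA together held medians of 0.115% and 0.0771% of the UMIs in Shox2-rich and 0.0928% and 0.0731% in Rxfp1-rich neurons. The camera adjusted p of these remaining lists ranged from 0.0917 for mitochondrially encoded genes to 0.899 for neurotrophic factor receptors, with 0.158 for noradrenergic genes, 0.148 for voltage-gated ion channels and 0.763 for cell adhesion molecules.

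Adjusted over the list alone, the counts higher and lower were 4 and 4 for sympathetic transcription factors, 0 and 3 for Hox genes, 0 and 1 for adrenergic receptors, 5 and 6 for peptide and hormone receptors, 7 and 3 for amine, purine, GABA and glutamate receptors and 12 and 10 for voltage-gated ion channels. They were 7 and 13 for axon guidance, 16 and 18 for cell adhesion, 0 and 9 for immediate early, 0 and 3 for mitochondrially encoded genes and 1 and 1 for fibroblast RNA, and unchanged for the other 9 lists. The median, mean and camera direction differed in sign for cell adhesion molecules, for neurotrophic factor receptors (-0.24, 0.12 and down), for satellite glia RNA (0.06, -0.16 and up) and for immune RNA (-0.11, -0.11 and up). With DESeq2, 25 of the genes named for this comparison no longer passed: Dkk2, Slc18a2, Cyb561, Sox4, Sox11, Ebf1, Hoxc6, Chgb, Pcsk1n, Chrna9, Chrna5, Chrm2, Cckar, Trpc6, Ntrk2, Ret, Btg2, Fosb, Junb, Csrp1, Gap43, Hspb1, mt-Atp6, mt-Co3 and Col1a2. Single neurons chosen by Shox2 and Rxfp1 UMIs also ended the calls of Slc18a2, Sox4, Sox11, Hoxc6, Npy, Pcsk1n, Cacna1e, Trpc6, Junb, Csrp1, Hspb1 and Col1a2, and turned mt-Atp6 and mt-Co3 upward. The call of mt-Co3 ended in all other tested alternatives for this comparison but RLE size factors and little other-cell RNA. Further calls ended were Chrm2 without the low-count filter, mt-Atp6 without the library block, Col1a2 with all UMIs, with at least 5000 UMIs and with little other-cell RNA, and Pcsk1n, Hspb1 and Col1a2 with another random split. Resolution 0.4 ended those of Ret and mt-Atp6, and thinning those of Slc18a2, Cyb561, Ebf1, Pcsk1n, Chrm2 and Gap43. Maoa, Hoxd4, Trpc7 and Fgfr2 passed with all UMIs, Fgfr2 in single neurons, mt-Co1 with RLE size factors and Dbh and Dbi at resolution 0.4.

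**Figure D3:**
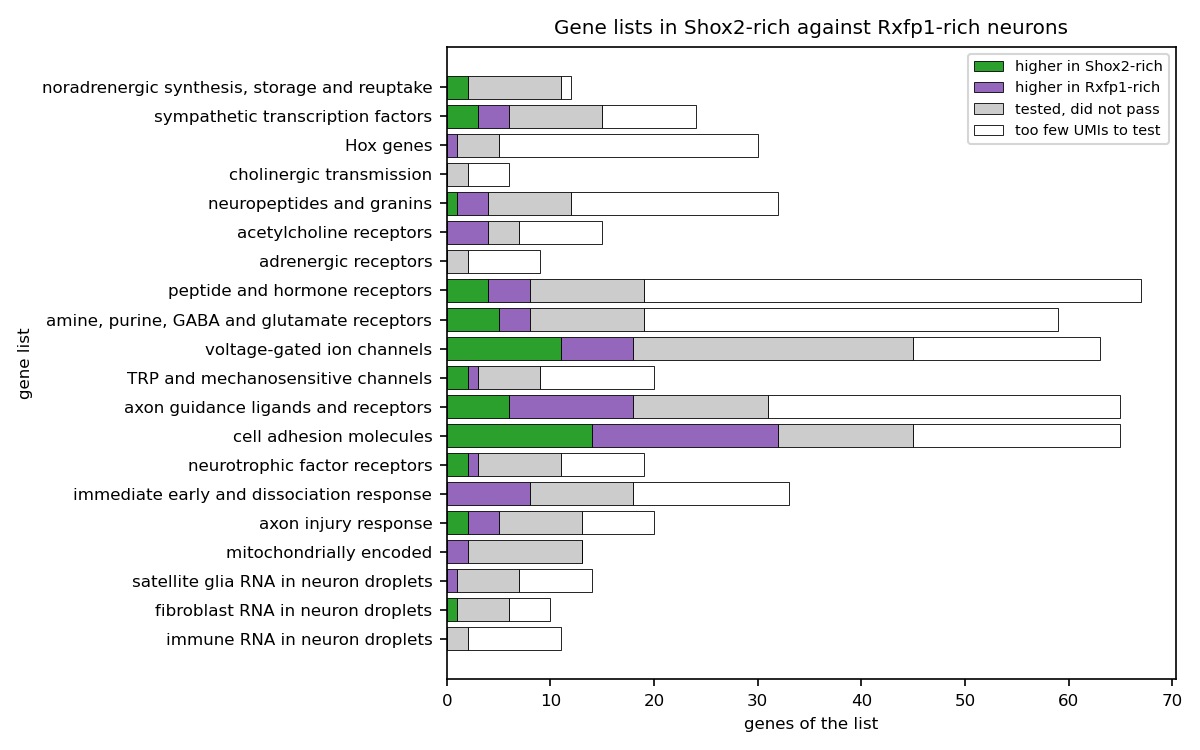
Genes of each list (horizontal axis, number of genes) that were higher in Shox2-rich neurons, higher in Rxfp1-rich neurons, tested without passing, or not tested for too few UMIs. Acetylcholine receptors have 4 members higher in Rxfp1-rich neurons and none higher in Shox2-rich neurons, and cell adhesion molecules have 14 and 18.

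Each neuron cluster was also compared with the other neurons by the same edgeR test. The other neurons took in low-UMI clusters and clusters that carried markers of other cells. For the Rxfp1-rich cluster they had median UMIs of 2227 and 2243 in library 1 and library 2, against 23342 and 21495.5 in the cluster. The counts below therefore also hold such differences between droplets. The direct comparison of Shox2-rich with Rxfp1-rich neurons called 964 genes. The Rxfp1-rich cluster, with 2719 genes higher and 3261 lower, was led by the sodium-proton exchanger gene Slc9b1 (3.52), Dkk2 (2.93) and Zfp804a (2.87), and the Shox2-rich cluster, with 2465 and 2888, by Vwc2 (3.76), Csmd3 (3.62) and Hs6st3 (3.57). The low-UMI cluster of 371 droplets, with 2668 and 2927, was led by the prohormone gene Pomc (3.69), Gpat2 (2.89) and Rpp25 (2.84). The low-UMI cluster of 718 droplets, with 2292 and 3126, was led by the haemoglobin genes Hba-a2 (3.83) and Hba-a1 (3.14), which belong to red blood cells, and by Cdk8 (3.01). A cluster of 107 droplets that carried satellite glia genes, with 357 and 905, was led by Erbb2 (5.43), a receptor chain through which neuregulin acts on Schwann cells, Fxyd3 (4.54) and Rlbp1 (4.40). The next clusters carried markers of other cells among their leading genes, with Cd74, Lyz2 and C1qa in that of 76, and held 30.9% and 26.0% of the tested neuron UMIs. A cluster of 82, with 675 and 624, was led by Bnc2 (3.82), Zfp536 (3.72) and Hmcn1 (3.71), and a cluster of 76, with 1846 and 1761, by Ptpn18 (4.45), the platelet factor gene Pf4 (4.32) and the smooth muscle actin gene Acta2 (4.31). A cluster of 79 droplets with few UMIs had no gene higher and 7 lower with edgeR, and 607 at an unadjusted p under 0.05. DESeq2 was not run on these clusters.

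Satellite glia and Schwann cells, the glia of neuronal somata and of axons, were compared last. Schwann cells pooled 1268 and 1229 non-myelinating with 199 and 214 myelinating cells. Lipg, the endothelial lipase gene, stood at 41.0 CPM ± 0.499 in satellite glia and 2.47 ± 0.234 in Schwann cells (SD, n = 2 libraries), a log2 fold change of 4.09 (SE 0.215). The sodium bicarbonate cotransporter gene Slc4a4 stood at 412 CPM on average against 32.6 (3.71), and Hes5, a target of Notch, at 40.4 ± 2.37 against 2.76 ± 0.584 (3.92). Mapk4 (3.96), Sh3rf3 (3.72), Cnmd (3.61), Fras1 (3.38) and Eepd1 (3.19) were also higher. Among the genes higher in Schwann cells, the claudin gene Cldn19 had -8.15, the myelin protein gene Ncmap -7.28, Gldn of the node of Ranvier -6.75, the plasmolipin gene Pllp -6.38, Emid1 -6.21, the promyelinating transcription factor gene Pou3f1 -6.16 and the myelin lipid hydroxylase gene Fa2h -5.96. In library 1 and library 2, Cldn19 had -7.50 and -9.75, Gldn -6.14 and -7.88, Pou3f1 -7.04 and -5.67 and Fa2h -6.57 and -5.60. Ncmap, Pou3f1, Cldn19 and Pllp were leading genes of the myelinating cluster. Against non-myelinating Schwann cells alone, a comparison chosen after seeing the data, Pou3f1 had -2.83 and Fa2h -2.39, and Cldn19, Ncmap, Gldn, Pllp, Emid1 and Slc36a2 had too few UMIs to test, so most of these differences rested on the myelinating cells. Slc36a2, an amino acid transporter gene with 1 UMI in satellite glia, had a ratio of 618 (110 to 24534) in favour of Schwann cells. Lipg lies on chromosome 18 from 74939322 to 74961263 and Cldn19 on chromosome 4 from 119255414 to 119262438 (GRCm38). With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 2070 genes were higher and 2121 lower in satellite glia of 14177 tested, 381 and 579 of them by over 2-fold, and 4180 of the 4191 had the same direction in both libraries. DESeq2 called 1448, all among the 4191.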

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

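Among the alternatives named here, those with at most 0.5% of other-cell RNA, with neurons of the Shox2-rich and Rxfp1-rich clusters alone, without the glia led by Ifit3, with non-myelinating Schwann cells alone, and with more clusters counted as Shox2-rich were chosen after seeing the data. For Shox2-rich against Rxfp1-rich neurons, DESeq2 called 260 genes instead of 964, all shared, and turned Cd74 to 0.10. Neurons thinned to 1000 UMIs gave 114, where fewer UMIs left 1127 genes to test. For satellite glia against Schwann cells, DESeq2 called 1448 of the 4191. With an estimated correlation, which had little power at 1 residual degree of freedom, 0 lists passed in either list comparison. The neuron share with doublets kept was 4.05% and 3.91% in the 2 libraries. The satellite glia share was 22.4% and 21.9% with doublets kept, 24.9% and 24.7% with at least 1000 genes, and 25.6% and 25.2% with clusters from all UMIs, while non-myelinating Schwann cells took 15.1% and 14.7%, 15.05% and 14.4%, and 13.8% and 13.3%. With at least 5000 UMIs the Shox2-rich share was 25.2% and 32.1% and the Rxfp1-rich share 29.0% and 29.5%, since fewer droplets stood in the denominator, and at resolution 0.4 the Shox2-rich share was 10.9% and 12.7%. It was 10.9% and 13.2% with the few-UMI cluster past the Shox2 margin, where 1064 genes were called, 92 named genes kept direction and call and Ret and mt-Co3 no longer passed while Dbh, Dbi and Dcn did, and 52.9% and 56.4% with every cluster past that margin. Directions turned as follows. Another random split gave Matn2 -0.30 and Sparc -0.078. Single neurons chosen by Shox2 and Rxfp1 UMIs gave Hoxd4 0.18, Slc10a4 0.19, Ache 0.10, mt-Atp6 0.36, mt-Co3 0.40, mt-Co1 0.32, mt-Nd4 0.40, Matn2 -0.24, Sparc -0.089, Dcn -0.33 and Apoe -0.12. Neurons with little other-cell RNA gave Cd74 1.28 and Apoe -0.041. Neurons of the 2 clusters alone against non-neuronal cells gave Hoxc9 -0.13, Adra2a -0.14 and mt-Co3 -0.17. For every other change above, the cause was not tested. Leaving out a library left no residual degrees of freedom and gave log2 values without a test. Without library 1 and without library 2, these lay over 1 SD between libraries from the fit for 53 and 54 of the named genes of neurons, 25 and 24 of the neuron populations and 13 and 13 of the glia. The fit was scaled by TMM and the single-library values were not, so these counts also hold the difference in scaling. Slc18a2 in neurons, for example, had 2.99 and 3.09 in the libraries, both above the fit of 2.91. The counts of called genes ranged from 8966 to 14485 for neurons, from 749 to 1207 for the neuron populations apart from DESeq2 and thinning, and from 3246 without the library block to 5522 with all UMIs for the glia apart from DESeq2. Without the library block 856 genes were called for the neuron populations and 12760 for neurons. Of the named genes of the neuron populations, 96 kept direction and call with RLE size factors, 95 without the low-count filter, 91 with all UMIs and 71 with DESeq2, which ended 25 calls. For neurons 81 did so with DESeq2, and for glia 16 did so in each tested alternative but that with non-myelinating Schwann cells alone, where 3426 genes were called, 10 named genes did so and the others had too few UMIs to test. The filter under 10% mitochondrial UMIs removed no cell and says nothing on stability. At this depth 51% of simulated 2-fold changes and 96.5% of 4-fold changes were recovered for the neuron populations, against 70.5% and 86% for neurons.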

Other observations

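The genes of this part were chosen after the data were seen, apart from marker genes. Some genes for growth factors of neurons were highest in the vessel wall. Ntf3, a neurotrophin, stood at 59.9 CPM ± 0.673 and Nrtn, a ligand of the Ret system, at 17.6 ± 0.292 in pericytes or smooth muscle cells (SD, n = 2 libraries, all UMIs). Kitl, the ligand of the mast cell receptor Kit, was highest in endothelial cells with 910 ± 8.78, and stood at 406 ± 29.5 in Shox2-rich and 267 ± 15.7 in Rxfp1-rich neurons. Cxcl12, a chemokine, was highest in endothelial cells with 1401 ± 86.1. Il34 and Csf1 encode ligands of the macrophage receptor Csf1r. Il34 was highest in pericytes or smooth muscle cells with 263 ± 0.0697, and Csf1 in mast cells with 273 ± 73.9. Sct, the ligand of the secretin receptor, reached 7.18 ± 0.891 in dendritic cells, and the relaxin genes Rln1 and Rln3 gave no UMI in either neuron population.

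The vesicular monoamine transporter gene Slc18a1, known from chromaffin cells, stood at 322 CPM ± 60.8 in Shox2-rich and 57.8 ± 24.1 in Rxfp1-rich neurons on the tested UMIs, a log2 fold change of 2.45 (SE 0.185), and at 7.58 ± 1.08 in endothelial cells over all UMIs. Prom1, a membrane glycoprotein, had a log2 fold change of -3.49 (SE 0.281). Of all kept cells, 42.5% and 42.1% in the 2 libraries had UMIs of Xist and none of the Y-linked genes, 29.5% and 29.8% had the reverse and 4.88% and 4.54% had both, as a suspension from animals of both sexes gives. Ifit3 stood at 1361 CPM ± 35.4 in the satellite glia cluster led by it, against 70.4 ± 0.875 in another satellite glia cluster, 1940 ± 390 in the fibroblast cluster led by Plac8, 161 ± 32.0 in macrophages, 4.71 ± 1.09 in Shox2-rich and 2.99 ± 0.00444 in Rxfp1-rich neurons.

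In the following paragraphs, the tests of free RNA in the cluster of 718 droplets, of one animal, of a difference between the libraries, of RNA of other cells and of neurons paired by UMIs were chosen only after the result was seen, and the other tests before. Apart from the medians of the immediate early list, the tests on UMIs used all of them, so also those that formed the clusters. The design holds 1 group, so no biological explanation was tested for any of these patterns.

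Most neuron-like droplets held few UMIs and little Malat1. Droplets of neuronal cytoplasm without a nucleus may be the source: genes over 200 kb lay below genes under 20 kb by -3.79 log2 units in library 1 and -3.99 in library 2 in the medians of the 2 low-UMI clusters against the Rxfp1-rich and Shox2-rich clusters. This test leans on reads in introns, and whether these were counted is not given in the sources used here. It used all UMIs, so also those that formed the clusters compared. It does not tell such droplets from free RNA, which was weighed separately. Free RNA with no neuron in the droplet needed a ratio of neuron to fibroblast markers within 1 log2 unit of that of endothelial cells. In the cluster of 371 this ratio lay 3.98 and 4.90 log2 units above that of endothelial cells. The droplets were named neuron-like by the same neuron markers on part of the same UMIs, so a raised ratio was set in part by the naming. The ratio therefore weighs only weakly against free RNA in this cluster. For the cluster of 718 the same ratio lay 0.85 units above in library 1, within the bound for free RNA, and 1.48 above in library 2, past it but short of the 2 units set against free RNA, so neuronal fragments and free RNA cannot be told apart there.

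The satellite glia cluster led by Ifit3, Ifit1 and Isg15, genes that textbooks describe as induced by interferon, was weighed against 3 technical explanations. If the cells came from one animal, they would be of one sex, but cells with Y-linked UMIs alone were 44.4% and 41.9% of those with UMIs of one sex. RNA of macrophages would raise macrophage markers by at least 2-fold over the other satellite glia cluster, but their ratio was 1.38 in library 1 and 0.814 in library 2. A difference between the libraries is set aside by the shares of 3.94% and 3.70%, a ratio of 1.06. What started the genes in these cells stays open, including the handling of the tissue, which was not tested.

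Of the 18 tested immediate early and dissociation response genes, 8 were lower in Shox2-rich than in Rxfp1-rich neurons and 10 did not pass. The list passed camera with the preset correlation but not with an estimated one (adjusted p = 0.895), which had little power at 1 residual degree of freedom. DESeq2 ended the calls of Btg2, Fosb and Junb. RNA of other cells in Rxfp1-rich droplets would need to reach 6.13% to give the Fos difference, and abundant satellite glia and fibroblast genes rose by a median of -0.0325 of what that needs, although 1 of the 15 genes rose by more than the need. Deeper Rxfp1-rich neurons are argued against in library 2, where both populations had like depths and the median of the 18 tested members was -0.92 log2 units with 17 lower. In library 1, where Rxfp1-rich neurons were deeper, the median was -0.449 with 12 lower. It was -0.447 among 49 pairs of neurons of like UMIs there, but with a counting interval from -1.14 to 0.22, so depth and another difference cannot be told apart for library 1. The median mitochondrial share was 1.57% and 0.970% in Rxfp1-rich and 1.23% and 0.764% in Shox2-rich neurons, and cell quality was not tested as the source. A difference in how the populations responded to dissociation was not tested and stays open, as does a biological difference between them.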
